A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

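RNA-seq was measured in 6 libraries of budding yeast (Saccharomyces cerevisiae). There were 3 libraries from log-phase cells, which were growing actively at an OD600 of 0.8 to 1.0, and 3 from quiescent cells, the dense fraction of a stationary culture collected at day 7 and purified on density gradients. Cultures were grown at 30 C in rich medium, per the labels' protocols. The protocols also state that 5 ug of total RNA was depleted of ribosomal RNA, that 250 ng of the depleted RNA entered each library, and that the libraries were read on an Ion Proton instrument. They call the replicates biological and record the addition of ERCC spike-in RNA before depletion.

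The authors deposited a table of raw read counts per feature, per the file headers, with a feature length beside each count. The genome build was R64, per the submitters' processing notes. The aligner, the counting tool, the read length and the strand setting are not given in the sources used here. The table held 9891 rows. Of these, 520 had no read in any library, and 78 of those were named by gene symbols. A further 6 columns of per-sample values, which were TPM values, were not used. TPM (a length-scaled share of each library) was computed here from the deposited counts and lengths. The rows included protein-coding genes, the ribosomal DNA unit, tRNA, snoRNA, mobile elements and 2 kinds of unstable or unannotated transcript, the CUTs and SUTs. No row of the table carried an ERCC name, so the spike-ins were not used here.

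Row names were matched to locus tags of the R64 reference annotation for 6048 rows. The feature length was 1 base below the reference gene span in 6012 of them, and these spans include introns. Reads within an intron of a gene, among them those of an intron-encoded snoRNA, can therefore enter its count. Near-identical genes such as ENO1 and ENO2, SSA1 and SSA2, EFT1 and EFT2 or the paired ribosomal protein genes share reads, so the split between such copies is uncertain. In rows of identical sequence, counts equalled each other in 0 of 53 comparisons within a library for the ribosomal DNA unit and 1 of 56 for genes, and in 46 and 45 of these they differed by no more than sampling noise (chi-square p of 0.05 or more). Shared reads were therefore divided among such copies, not counted at each. Overlapping and antisense features are uncertain as well, because the strand setting is not known.

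Rows with a mean TPM of at least 1 over the 6 libraries were tested, which left 7305 rows, 5608 of them genes. A gene is a nuclear or mitochondrial protein-coding row. The main test was the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts, two-sided, with TMM scaling over all tested rows and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, at a threshold of 0.05. Log2 fold changes are quiescent minus log, and their standard errors (SE) were taken from the fold change and its F statistic. Levels are normalized CPM (counts scaled to library size), given as mean ± SD. The biological coefficient of variation was 0.264.

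The design fixed before the data were examined assumed TPM values and limma on log2(TPM + 1). It named the edgeR test for the case that the table also held whole counts, which it did. The definition of a gene, TMM over all tested rows and the way camera was run on counts were chosen after the table was seen.

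The 27 gene lists were fixed before the data were examined. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists with at least 5 tested members. Members that passed the test over all tested rows were counted as having risen or fallen. The counts adjusted over the list alone were also made. Shares of TPM or counts and single values were compared by exact two-sided permutation tests, whose smallest possible p with 3 libraries against 3 is 0.1.

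Named genes followed a rule fixed beforehand. It took the 6 rising and 6 falling genes of largest change with an adjusted p under 0.05, at least 10 TPM in the higher group and no overlap between the groups, leaving out rRNA, tRNA, spike-in and dubious rows. It also took from each list the 2 called members of largest change in the direction of most calls (1 of each direction after a tie), with at least 10 TPM in the higher group. The strain check genes, members of the RNA polymerase II, H3 methylation and histone lists, and ACT1, TDH3, HSP12 and HSP26 completed it. From those 3 lists, the members that passed and SET1 and RPB4 are named. The other members of the lists were left out after their values were seen.

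The alternatives were other pseudocounts, filters and scalings, limma without a trend, a minimum fold change, the replicate number as a block, and each library left out in turn. For the lists they were camera with an estimated correlation or on ranks, and fry, which tests a list against no change and not against the other genes. Alternatives added after seeing the data were DESeq2 1.42.0, total-count scaling, TMM from protein-coding genes, camera among genes only and shares of counts. Limma on log2(TPM + 1), which the design named for a table without counts, was added as an alternative then as well.

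Each test was tried on simulated counts of 7305 rows with 200 changed genes. For the comparison of quiescent with log cells, the edgeR test recovered 100 of 100 genes changed 4-fold and 47 of 100 genes changed 2-fold, with 4 false calls among 5608 genes. Camera recovered both lists that had been changed 2-fold and called none of the others. The gene trial used log-cell levels for both groups and the same spread for all rows. Its 200 changed genes rose and fell in equal number, and all other rows were unchanged. The 4 false calls are therefore not the error rate of the real comparison, where most genes changed and calls depended on the scaling. In the list trial each gene was also drawn independently, and genes outside those lists were unchanged. That trial therefore does not show how camera performs where genes are correlated. Total counts ranged from 8894585 to 14213993 per library. Replicate libraries differed by more than sampling noise: chi-square per degree of freedom over protein-coding genes was 13.2 to 51.5, so none was treated as a duplicate. P-values of the gene tests cover the spread between these libraries. Those of camera with the preset correlation set the genes of a list against other genes. Those of the chi-square tests on identical rows refer to sampling noise.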

Results

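The series compared the transcriptome of yeast growing in log phase with that of purified quiescent cells, non-dividing cells that form in a starved culture and can resume growth. Per the labels, the strain expresses a 9Myc-tagged RNA polymerase II subunit, RPB3, and takes its histones H2A and H2B from plasmids. Total counts were 12395743, 10476761 and 14213993 in log replicates 1, 2 and 3, and 8894585, 12696572 and 12245637 in quiescent replicates 1, 2 and 3. Across nuclear protein-coding genes, Pearson's r of log2(TPM + 1) was 0.981 to 0.987 among log libraries, 0.949 to 0.967 among quiescent libraries and 0.298 to 0.350 between the groups. These are correlations across genes, which are not independent replicates.

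The makeup of the libraries differed between the states. Protein-coding genes held 24.1% ± 2.10 of TPM in log cells and 7.01% ± 1.80 in quiescent cells (SD, n = 3 each). Cytosolic ribosomal protein genes held 6.64% ± 0.617 and 0.229% ± 0.0577 of TPM. As shares of counts, protein-coding genes held 67.0% ± 4.16 and 32.2% ± 6.36, and the snoRNA and snRNA rows, small RNAs that guide rRNA modification and splicing, held 8.19% ± 1.11 and 17.2% ± 3.80. The groups did not overlap in these 4 shares, and the exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow. As a share of TPM, the snoRNA and snRNA rows held 20.8% ± 1.29 and 23.8% ± 6.75, and there the groups overlapped (exact permutation p = 0.5). Rows of the ribosomal DNA unit varied widely within groups, with 12.7% ± 7.39 of counts in log and 29.9% ± 12 in quiescent libraries (exact permutation p = 0.2). Within the unit, the 5.8S rRNA rows held 3.08% ± 2.22 and 16.2% ± 6.09 without overlap (exact permutation p = 0.1). The 18S and 25S rRNA rows held 2.58% ± 1.86 and 2.44% ± 3.15 (exact permutation p = 0.9).

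**Figure D1:**
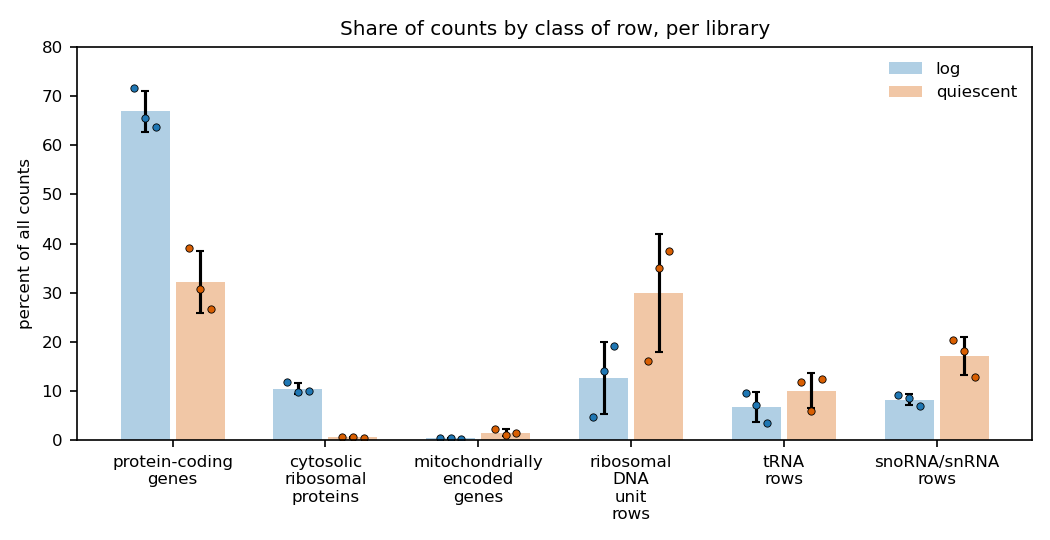
Percent of all counts (y axis) held by 6 classes of row (x axis) in log and quiescent libraries. Bars are means of 3 libraries, error bars SD and points single libraries. The protein-coding share was 63.7% to 71.7% in log and 26.6% to 39.1% in quiescent libraries.

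Most genes differed between quiescent and log cells. Of 5608 genes tested, 4080 changed in the edgeR quasi-likelihood test, of which 1781 rose and 2299 fell in quiescent cells. ADY2 (YCR010C, chromosome III, 11.44 on the log2 scale, SE 0.41), an acetate transporter gene, went from 0.659 ± 0.151 CPM to 1840 ± 458 CPM (SD, n = 3 each). It was followed by RGI2 (YIL057C, 11.08, SE 0.31), SPG1 (YGR236C, 10.63, SE 0.36), the hydrophilin gene SIP18 (YMR175W, 9.72, SE 0.35), SPG4 (YMR107W, 9.60, SE 0.44) and DPC7 (YKL065W-A, 9.18, SE 0.34). These 6 genes had 1 to 28 reads each in a log library, so their folds and order are imprecise. The enolase gene ENO2 (YHR174W, chromosome VIII) went from 11300 ± 2060 to 29.8 ± 11.5 CPM, a log2 fold change of -8.56 (SE 0.48). The Hsp70 chaperone gene SSA2 (YLL024C, -7.13, SE 0.36), the cell wall gene CIS3 (YJL158C, -7.08, SE 0.34), the plasma membrane proton pump gene PMA1 (YGL008C, -6.92, SE 0.34), SAH1 (YER043C, -6.77, SE 0.30) and INA1 (YLR413W, -6.68, SE 0.29) followed. ENO2, SSA2 and PMA1 have close copies whose reads may be shared. The adjusted p of these 12 genes was at most 2.18e-07.

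**Figure D2:**
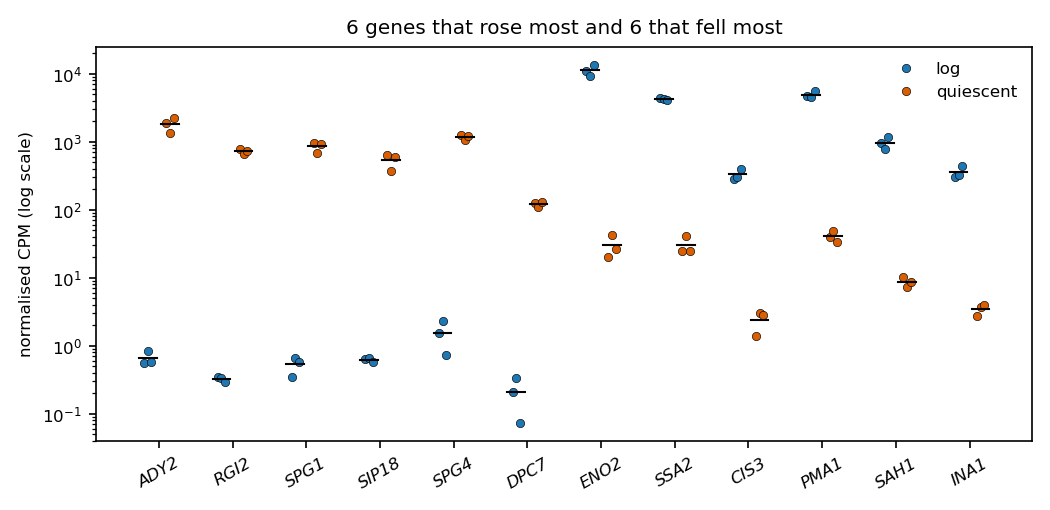
Normalised CPM (log-scaled y axis) of the 6 genes that rose most and the 6 that fell most (x axis). Points are single libraries and lines are group means of 3. In each gene the values of the groups did not overlap.

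The split of risers and fallers depended on the scaling. Limma on log2(TPM + 1), the design's test for a table without counts, was added as an alternative after the data were seen. With it, 799 genes rose and 3372 fell, so 19.2% of the calls were upward against 43.7% in the edgeR test. The median log2 fold change of all genes was -0.21 in the edgeR test, -0.45 with total-count scaling, -0.01 with TMM from protein-coding genes and -0.98 on the TPM scale. All changes below are relative to the TMM scaling. ACT1 fell by 4.02 (SE 0.30), TDH3 fell by 5.35 (SE 0.43), and the small heat shock protein genes HSP12 and HSP26 rose by 7.38 (SE 0.30) and 5.84 (SE 0.31).

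Genes for the use of acetate, ethanol and fatty acids rose together. All 22 members of the gluconeogenesis and glyoxylate list rose (median 5.08, camera adjusted p = 1.16e-18; adjusted p = 0.115 with an estimated correlation), among them ADY2 and the acetyl-CoA synthetase gene ACS1 (8.24, SE 0.45). Of 34 genes of fatty acid oxidation and the peroxisome, 31 rose and 1 fell (median 3.01, adjusted p = 1.62e-14; adjusted p = 0.115 with an estimated correlation). The peroxisomal catalase gene CTA1 rose by 8.93 (SE 0.35) and the thiolase gene POT1 by 8.56 (SE 0.44). Of 21 glycolysis and fermentation genes, 17 fell and 3 rose (median -3.77, adjusted p = 2.73e-07; adjusted p = 0.115 with an estimated correlation), and PGK1 (-6.62, SE 0.49) was second in the list after ENO2. Of 21 trehalose and glycogen genes, 18 rose and 3 fell (median 2.71, adjusted p = 5.64e-07; adjusted p = 0.115 with an estimated correlation). GAC1, a subunit of the phosphatase acting on glycogen synthase, rose by 7.50 (SE 0.35) and the trehalase gene ATH1 by 5.15 (SE 0.23). The hexose transporter list went both ways, with 4 members risen and 4 fallen of 10 (adjusted p = 0.204). HXT5 rose by 8.80 (SE 0.36) and HXT3 fell by 4.55 (SE 0.34).

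Mitochondrial genes did not move as 1 group. Of 40 nuclear genes of the respiratory chain and ATP synthase, 21 rose and 10 fell (median 0.48, adjusted p = 0.0124; adjusted p = 0.181 with an estimated correlation). This call was lost on the TPM scale, where the list's median was -0.52. CYB2 (lactate dehydrogenase, 7.66, SE 0.46) and NDE2 (external NADH dehydrogenase, 6.98, SE 0.27) led it. The 20 genes of the tricarboxylic acid cycle were split into 9 risen and 9 fallen (adjusted p = 0.887), with the citrate synthase gene CIT3 at 8.84 (SE 0.53) and the isocitrate dehydrogenase gene IDH2 at -3.07 (SE 0.28). Of 8 mitochondrially encoded genes, 7 rose (median 1.51), including COX1 (2.38, SE 0.34) and COX3 (2.26, SE 0.27). The list missed the threshold (adjusted p = 0.0604; adjusted p = 0.558 with an estimated correlation), and passed it without quiescent replicate 2 (adjusted p = 0.00626), on the TPM scale (0.0174), with quantile normalization (0.0026), without a filter (0.0438), with total-count scaling (0.0497) and with camera on ranks (0.017). Fry, which tests a list against no change and not against the other genes, called it as well (0.0226).

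Stationary-phase and autophagy genes rose, and stress genes went both ways with most rising. Of 55 heat shock and general stress genes, 36 rose and 14 fell (median 1.33, adjusted p = 1.19e-06; adjusted p = 0.122 with an estimated correlation), led by SIP18 and DDR2 (7.98, SE 0.27). Among chaperone genes of that list, SSA2, SSE1 (-5.47), SSA1 (-5.40), HSC82 (-5.33), HSP82 (-2.15) and HSP104 (-0.77) fell, and HSP26 (5.84) rose. Those that fell were chosen after their values were seen and do not stand for all chaperone genes of the list. Of 30 stationary-phase and quiescence genes, 25 rose and 1 fell (median 2.58, adjusted p = 2.93e-12; adjusted p = 0.104 with an estimated correlation), led by SPG1 and SPG4. Genes of this list are named for earlier work on the same state, so the direction is not independent evidence. Of 35 autophagy genes, 29 rose and 1 fell (median 2.03, adjusted p = 7.41e-09; adjusted p = 0.115 with an estimated correlation), with ATG39, a receptor for nuclear autophagy, at 7.62 (SE 0.26) and ATG34 at 5.38 (SE 0.30). The 11 vacuolar protease genes measured gave 5 risen and 2 fallen (adjusted p = 0.162), led by PRB1 (3.93, SE 0.27) and YPS1 (2.28, SE 0.23), the latter a protease of the cell surface. That list was called upward with quantile normalization (adjusted p = 0.00992), and by fry against no change (0.000242). Of 36 proteasome genes, 19 fell and 2 rose (median -0.57, adjusted p = 0.210), with RPN9 at -1.49 (SE 0.18) and RPN7 at -1.44 (SE 0.18). The proteasome list was called downward on the TPM scale (adjusted p = 0.0164), and by fry against no change (0.0155).

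Genes of ribosomes, translation and biosynthesis fell. Of 137 cytosolic ribosomal protein genes 136 fell (median -4.36, adjusted p = 9.74e-57; adjusted p = 0.115 with an estimated correlation), with RPS22A at -6.59 (SE 0.25) and RPP0 at -5.80 (SE 0.28). The 1 that did not pass was RPS22B, which is named because it was the exception. Of 110 ribosome biogenesis genes, 107 fell (median -2.18, adjusted p = 2.09e-15; adjusted p = 0.254 with an estimated correlation), led by the nucleolar protein genes NOP1 (-5.50, SE 0.41) and NOP58 (-4.36, SE 0.24). Of 19 subunit genes of RNA polymerases I and III, 18 fell (median -1.80, adjusted p = 0.000195; adjusted p = 0.260 with an estimated correlation), with RPA12 at -3.79 (SE 0.26) and RPA135 at -3.56 (SE 0.33). All 35 translation factor genes fell (median -2.56, adjusted p = 2.90e-12; adjusted p = 0.188 with an estimated correlation), among them the elongation factor genes YEF3 (-6.18, SE 0.41) and EFT1 (-4.30, SE 0.29). Of 73 amino acid biosynthesis genes, 60 fell and 6 rose (median -2.29, adjusted p = 4.83e-13; adjusted p = 0.115 with an estimated correlation), with HIS1 at -5.69 (SE 0.29) and SAM1 at -5.21 (SE 0.27). Of 23 ergosterol genes, 21 fell (median -2.81, adjusted p = 6.30e-09; adjusted p = 0.115 with an estimated correlation), with ERG4 at -5.72 (SE 0.48) and MVD1 at -4.76 (SE 0.21).

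**Figure D3:**
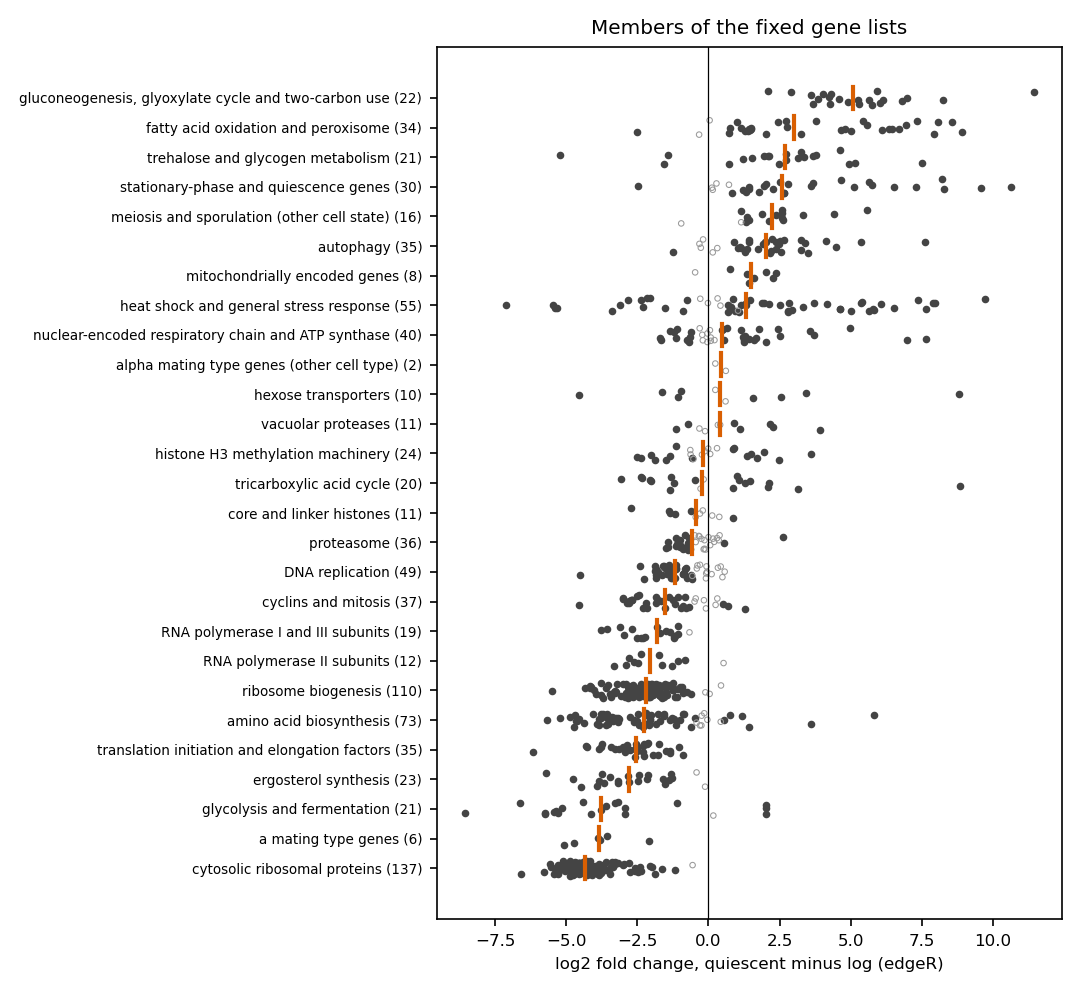
Log2 fold change, quiescent minus log (x axis), of every tested member of the 27 fixed lists (y axis, number tested in brackets). Filled points passed the edgeR test, open points did not, and bars are medians. The medians ranged from -4.36 in cytosolic ribosomal proteins to 5.08 in the gluconeogenesis list.

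The series set the transcriptome beside the occupancy of RNA polymerase II and of methylated histone H3, so the genes of these proteins were examined. Of 12 RNA polymerase II subunit genes, 11 fell (median -2.07, adjusted p = 0.00161; adjusted p = 0.188 with an estimated correlation). The largest falls were in RPB8 (-3.32, SE 0.19) and RPC10 (-2.90, SE 0.32), followed by RPO26 (-2.78, SE 0.23), RPB10 (-2.62, SE 0.26), RPB9 (-2.48, SE 0.27) and RPB5 (-2.39, SE 0.31). The catalytic subunit genes RPO21 (-1.75, SE 0.22) and RPB2 (-1.62, SE 0.21) fell less. RPB3, the tagged subunit, went from 16.0 ± 2.86 to 7.58 ± 2.42 CPM (-1.08, SE 0.29, adjusted p = 0.00776). RPB11 fell by 1.27 (SE 0.29), a call lost with a filter of 10 TPM (-0.79, adjusted p = 0.0529). RPB4, whose product forms a dissociable pair with that of RPB7, did not pass at 0.53 (SE 0.22, adjusted p = 0.0521) and lay at -0.47 on the TPM scale. It passed upward in 7 settings, from 0.57 (adjusted p = 0.0458) with scaling by rows outside rRNA, tRNA, mitochondrial genes and ribosomal proteins to 1.0 (adjusted p = 0.00453) with a filter of 10 TPM. The others were median-of-ratios size factors (0.59), DESeq2 (0.59), TMM from protein-coding genes (0.73), without quiescent replicate 3 (0.75) and quantile normalization (0.78). RPB7 was at -0.83 (SE 0.24, adjusted p = 0.0118), a call lost with a filter of 10 TPM (-0.35, adjusted p = 0.256), with quantile normalization (-0.53, adjusted p = 0.0578), and without log replicate 3 (-0.61, adjusted p = 0.0692) or quiescent replicate 3 (-0.59, adjusted p = 0.0546).

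The 24 genes of the H3 methylation machinery went both ways, with 8 risen and 8 fallen (median -0.18, adjusted p = 0.782). Of the methyltransferase genes, DOT1 (H3K79) fell by 2.51 (SE 0.35) and SET2 (H3K36) fell by 1.5 (SE 0.20), and SET1 (H3K4) did not pass at 0.30 (SE 0.18, adjusted p = 0.167). SET1 passed upward with TMM from protein-coding genes (0.50, adjusted p = 0.0262) and downward on the TPM scale (-0.59, adjusted p = 0.0488). The demethylase genes GIS1 (3.59, SE 0.28), RPH1 (1.94, SE 0.18), JHD2 (1.69, SE 0.20) and JHD1 (0.86, SE 0.20) rose, although JHD1 lay at -0.11 on the TPM scale. Within the SET1 complex, BRE2 (1.5, SE 0.22) and SPP1 (1.36, SE 0.22) rose, and SWD2 (-1.89, SE 0.28), SWD3 (-2.36, SE 0.36) and SDC1 (-1.15, SE 0.30) fell. LGE1, a partner of the H2B ubiquitin ligase, rose by 2.48 (SE 0.24). The ubiquitin protease gene UBP10 rose by 0.89 (SE 0.17) and lay at -0.12 on the TPM scale. CTR9 (-2.03, SE 0.21), CDC73 (-1.34, SE 0.24) and RTF1 (-0.57, SE 0.18) of the Paf1 complex fell. The RTF1 call was lost with TMM from protein-coding genes (-0.36, adjusted p = 0.105), and without log replicate 3 (-0.40, adjusted p = 0.124) or quiescent replicate 3 (-0.54, adjusted p = 0.0554). BRE2 (0.38), SPP1 (0.27) and JHD2 (0.47) no longer passed on the TPM scale.

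Of 11 histone genes, 5 fell and 1 rose (median -0.45, adjusted p = 0.297). The list and its test include HTA2 and HTB2, which the strain is labelled as lacking. They also include HTA1 and HTB1, labelled as carried on plasmids. The median was the value of HTA1, and HTB1 was among the 5 that fell, a call lost in several settings given below. The H4 genes HHF2 (-2.74, SE 0.24) and HHF1 (-1.38, SE 0.24), the H3 gene HHT2 (-1.19, SE 0.17) and the H2A variant gene HTZ1 (-1.34, SE 0.23) fell. The linker histone gene HHO1 rose by 0.85 (SE 0.21), and lay at -0.17 on the TPM scale. With quantile normalization, HHF1 (-0.55) and HHT2 (-0.31) no longer passed.

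Most cell cycle genes fell. Of 49 DNA replication genes, 36 fell (median -1.18, adjusted p = 0.00122; adjusted p = 0.115 with an estimated correlation), led by RNR1 (-4.52, SE 0.22), a ribonucleotide reductase subunit, and POL30 (-2.40, SE 0.20), the sliding clamp. Of 37 cyclin and mitosis genes, 28 fell and 3 rose (median -1.52, adjusted p = 0.000232; adjusted p = 0.135 with an estimated correlation), with the cyclin genes CLB2 at -4.55 (SE 0.23) and CLN2 at -3.01 (SE 0.29). All 6 measured a mating type genes fell (median -3.86, adjusted p = 4.27e-05; adjusted p = 0.115 with an estimated correlation), with MFA2 at -5.08 (SE 0.33) and the pheromone receptor gene STE2 at -4.73 (SE 0.24). Neither of the 2 measured genes of the alpha type passed. Of 16 meiosis and sporulation genes measured, 14 rose (median 2.25, adjusted p = 0.000616; adjusted p = 0.115 with an estimated correlation), among them DMC1, a meiotic recombinase, from 1.54 ± 0.323 to 74.6 ± 20.8 CPM and IME1, a regulator of meiotic entry, from 3.15 ± 2.34 to 67.2 ± 11 CPM. The other 27 members of that list were below the TPM minimum. That minimum was a mean over both groups, so a gene nearly silent in log cells could pass through its quiescent values. The count that rose and the median can therefore be partly set by the filter.

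No list was called when camera estimated the correlation between genes (smallest adjusted p = 0.104). DNA replication lost its call there too (adjusted p = 0.115), although its estimated correlation of -0.0109 lay below the preset 0.01. Losing a call in this setting therefore does not show that correlation between genes made the call. With a filter of 10 TPM, the calls of RNA polymerases I and III (adjusted p = 0.0793), RNA polymerase II (0.13) and DNA replication (0.375) were lost. Adjusted over the list alone, the counts of risen and fallen members were the same in 22 of the 27 lists. The others were 1 risen and 11 fallen for RNA polymerase II, 37 and 14 for heat shock, 2 and 18 for the proteasome, 5 and 4 for hexose transporters and 0 and 22 for ergosterol.

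The strain is labelled as lacking the chromosomal HTA1-HTB1 and HTA2-HTB2 pairs and as carrying HTA1-HTB1 on plasmids. HTA1 (chromosome IV, 915530 to 915928) stood at 456 ± 27.0 CPM in log and 335 ± 32.6 CPM in quiescent cells (-0.45, SE 0.19, adjusted p = 0.0614), and HTB1 (chromosome IV, 914317 to 914712) at 395 ± 33.4 and 256 ± 47.7 CPM (-0.63, SE 0.21, adjusted p = 0.0225). HTA1 passed downward on the TPM scale (-1.46, adjusted p = 0.00292) and without a filter (-0.60, adjusted p = 0.027). The HTB1 call was lost with quantile normalization (-0.09, adjusted p = 0.814), a filter of 10 TPM (-0.14, adjusted p = 0.5) and TMM from protein-coding genes (-0.42, adjusted p = 0.0912), and without log replicate 1 (adjusted p = 0.0791), log replicate 3 (0.0683), quiescent replicate 1 (0.0679) or quiescent replicate 3 (0.113). HTA2 (chromosome II, 235394 to 235792) stood at 11.1 ± 1.91 and 12.1 ± 2.77 CPM, and HTB2 (chromosome II, 236492 to 236887) at 7.02 ± 1.59 and 9.15 ± 2.97 CPM, neither past the threshold (adjusted p = 0.682 and 0.304), although HTA2 passed downward on the TPM scale (-0.81, adjusted p = 0.01). Counts at HTA2 were 2.45% ± 0.557 of those at HTA1 in log and 3.59% ± 0.511 in quiescent libraries, and counts at HTB2 were 1.77% ± 0.284 and 3.69% ± 1.39 of those at HTB1 (SD, n = 3 each, exact permutation p = 0.1 for both). Of the marker genes, LEU2 went from 55.7 ± 3.44 to 15.2 ± 6.29 CPM, HIS3 from 374 ± 28.8 to 69.7 ± 10.3 CPM, URA3 from 62.0 ± 16.7 to 10.7 ± 1.72 CPM and TRP1 from 5.03 ± 0.265 to 15.4 ± 2.28 CPM. The first 3 fell (-1.87, -2.42 and -2.53), and TRP1 rose by 1.61 (SE 0.24), a call lost on the TPM scale (0.47, adjusted p = 0.0712).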

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

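DESeq2, total-count scaling, TMM from protein-coding genes, camera among genes only and shares of counts were chosen after the data were seen. So was the use of limma on log2(TPM + 1) as an alternative, although the design named it for a table without counts. The other settings were planned. The count of changed genes stayed within 1.5 times 4080 except with a filter of 10 TPM (1670 changed, 669 rising, 1001 falling), which tests fewer genes, and with a minimum log2 fold change of 1 (2538, 1053 and 1485), which asks for more. Rising genes numbered 799 with limma on log2(TPM + 1), 781 with pseudocount 0.1, 803 with pseudocount 5 and 783 without trend. Of the calls of limma on log2(TPM + 1), 3098 were shared with the edgeR test, and all 3098 had the same direction. Without 1 replicate, 3737 to 4064 genes changed, 1586 to 1762 rose, 2124 to 2314 fell and 19 to 20 lists were called. Camera with an estimated correlation called 0 lists of 26, fry, whose null is no change, 24 and the other settings 14 to 21. ERCC scaling was not run, because no row of the table used carries a spike-in.

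Same-numbered libraries did not deviate together (r of 0.048, -0.097 and -0.047 for numbers 1, 2 and 3), and not every library correlated best with its own number. With the replicate number as a block, 3929 genes changed, 1681 rose and 2248 fell, and 19 lists were called.

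The shares of protein-coding genes, ribosomal proteins, mitochondrially encoded genes and snoRNA and snRNA rows, quiescent minus log in percentage points, changed size but not direction. TPM without rRNA and tRNA rows gave -27.7 for protein-coding genes, -12.5 for ribosomal proteins, 0.204 for mitochondrially encoded genes and 25 for snoRNA and snRNA rows. Shares of counts gave -34.8, -9.93 and 1.14 for the first 3. The tRNA rows did change direction. They held 33.3% of TPM in log and 30.8% in quiescent libraries (exact permutation p = 0.9), but 6.74% and 10.1% of counts (exact permutation p = 0.3). Mean r within log libraries was 0.973 by Spearman and 0.978 with pseudocount 0.1, and 0.935 by Spearman within quiescent libraries. Between groups it was 0.303 by Spearman, 0.309 with pseudocount 0.1 and -0.124 with a filter of 10 TPM. That filter was on the mean over both groups, so it kept genes high in either state, and such selection can lower this r. The value therefore does not show that abundant genes were inversely related between the states. The cause was not tested.

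Of the named genes, some changed sign. With limma at pseudocount 1, 0.1 and 5 and without trend, HTA2 was at -0.81, -0.89, -0.59 and -0.81, HTB2 at -0.56, -0.65, -0.35 and -0.56, and RPB4 at -0.47, -0.51, -0.36 and -0.47. In the same order SET1 was at -0.59, -0.71, -0.34 and -0.59, JHD1 at -0.11, -0.14, -0.05 and -0.11, UBP10 at -0.12, -0.13, -0.08 and -0.12, and HHO1 at -0.17, -0.18, -0.13 and -0.17. With pseudocount 1 the median of all genes lay at -0.98, so genes with small rises end below 0. HTA2 was also at -0.03 without a filter and -0.15 with total-count scaling, and HTA1 at 0.04 with a filter of 10 TPM. With that filter, TMM was recomputed over the rows kept, and HTA1, HTB1, RPB4, RPB7 and RPB11 all lay higher than in the main test. Their lost or gained calls there are therefore not separate results. With a minimum log2 fold change of 1, the calls of HTB1, RPB3, RPB7, RPB11, SDC1, CDC73, RTF1, JHD1, UBP10, HHT2, HTZ1 and HHO1 were lost. With total-count scaling, those of JHD1 (0.65), UBP10 (0.68) and HHO1 (0.66) were lost. With limma at pseudocount 0.1 and 5 and without trend, HTA1 fell (-1.47, -1.44 and -1.46), and SET1 passed downward with pseudocount 5 alone of these (adjusted p = 0.0467). The proteasome list was called downward in the same 3 settings (adjusted p = 0.037, 0.00575 and 0.0164), and the mitochondrially encoded list upward (0.0258, 0.0103 and 0.0174). Against no change, fry also called the histone list downward (0.000435) and the hexose transporters upward (0.00345). In simulated counts for this comparison, 47 of 100 genes changed 2-fold were recovered, 24 of 50 below the median count and 23 of 50 above it, a split chosen after the results were seen.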

Other observations

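The tests of residual rRNA, of messenger RNA content, of intron-encoded snoRNAs, of the histone windows and background, and the counts over other splits were chosen after the results were seen.

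Rows outside the protein-coding genes moved as well. Of 501 SUT rows, stable unannotated transcripts, 252 rose and 35 fell (median 1.19 on the log2 scale). Of 314 CUT rows, cryptic unstable transcripts, 90 rose and 60 fell. Of 81 snoRNA and snRNA rows, 71 rose and 1 fell (median 1.26). Both mitochondrial rRNA rows rose. Of 21 Ty element rows, 16 fell and none rose (median -0.75), although copies of such elements share reads. With limma on log2(TPM + 1), the SUT rows gave 120 risen and 103 fallen, the CUT rows 38 and 118, the snoRNA and snRNA rows 5 and 1, and the Ty rows 0 and 21.

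Genes near chromosome ends were tested as a hypothesis written before the result was seen, namely that they rise relative to other genes. Of 161 tested genes within 20 kb of a chromosome end, 88 rose and 28 fell (median 0.72), against 1684 and 2271 of 5436 other nuclear genes (median -0.24). In log cells their median level was 10.5 CPM, against 22.3 CPM for the other genes. The TPM minimum was a mean over both groups, so genes nearly silent in log cells could pass through their quiescent values. The count that rose and the median can therefore be partly set by the filter. Camera gave p = 0.000839 with a preset correlation between genes and p = 0.233 with the estimated one of 0.0868. The hypothesis is thus met only with the preset, which takes genes as close to independent. As for the lists above, the loss with the estimated correlation does not show that correlation between genes made the call. The median lay above those of all 10000 random lists matched on expression, whose highest was 0.54, but such lists make no allowance for correlation between genes. Among members chosen after their values were seen, MSC1 (7.15) and PHO89 (5.31) rose, and HSP32 (5.64), HSP33 (5.39), ERR1 and ERR2 (4.70 and 4.84) rose too but have close copies that may share reads.

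Protein-coding genes held a lower share of counts in quiescent libraries. Residual rRNA and tRNA cannot be the whole cause, since outside those rows the share still differed by -29.3 percentage points (83.1% ± 0.577 in log, 53.8% ± 1.31 in quiescent cells, SD, n = 3 each). Log2 fold change did not follow feature length across 5597 genes, which are not independent (Spearman correlation of 0.01). This argues against a loss that grows with length among these genes. It cannot decide on RNA breakdown that lowers protein-coding genes of all lengths, because only such genes were compared. Less messenger RNA per quiescent cell stays open, because 0 spike-in rows were in the table used, and the biological difference between the states is untested on that scale.

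A few ribosomal protein genes fell far less than the rest, and those that host an intronic snoRNA, RPS22B (-0.56), RPL7A (-1.19) and RPL7B (-2.06), had a median 3.19 above that of the 134 other ribosomal protein genes. Intron retention in general is argued against, because intron-containing genes without a snoRNA differed from intronless ones by 0.08. A candidate explanation is that reads of the snoRNA were counted in the host. Outside the list, NOG2 (0.44) lay above the median of the rest of its list (-2.20), TEF4 (-2.13) and EFB1 (-2.15) lay above that of theirs (-2.57) but close to the upper quartile (-2.14), and ASC1 (-1.93) and IMD4 (-0.99), which are in no fixed list and so were not compared, fell. RPS9A (-1.64), RPL22B (-1.87) and RPS27A (-2.00) host none and also fell little (all genes here were chosen after their values were seen).

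Reads were counted at HTA2 and HTB2 although the strain is labelled as lacking both. Evenly spread background is argued against, because TPM there was at least 19.0 times that of the silent mating-type and MAT region rows. For HTA2, whether reads identical to HTA1 explain all counts stays open: 4.57% of its 50-base windows occur in HTA1, which at an even split of such reads gives 2.34%, against count ratios of 2.45% and 3.59%, but 18.1% of its 25-base windows do, and the read length is not known. For HTB2, reads of 50 bases or more identical to HTB1 cannot, since 0 of 347 windows are shared, but 4.3% of 25-base windows are, and 8.93% of 50-base windows lie within 2 mismatches (4.68% at an even split), so shorter or imperfectly aligned HTB1 reads could. Whether the aligner allowed that is not given in the sources used here, and RNA of another strain was not tested.

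The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The edgeR test called 4080 genes in the real split, which was the 1 split with as many, and at most 0 in the other splits, where 6 to 25 genes had an unadjusted p under 0.05 and no other tool was run. Camera called 19 lists in the real split and at most 19 in the others, and 5 of the 10 splits gave as many. Each other split sets 2 libraries of one state and 1 of the other against the reverse. Part of the real contrast therefore remains in it, and its lists are not those expected with no change. Mixing the states within a group also widens its spread, so few genes could be called there. The 0 calls of those splits therefore do not measure chance calls.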
